A study of Rattus norvegicus with 2 samples.

How the data were processed

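RNA labelled with Cy3 was hybridised to Agilent 1-colour miRNA arrays, 1 array labelled tumour and 1 array labelled normal, on 1 slide scanned in 1 scan. Per the labels, total RNA was isolated from 7 tumours and 7 normal tissues. Pooling is not given in the sources used here. The labelling kit named in the labels is one for messenger RNA amplification, and how the miRNA was labelled is not given in the sources used here. The deposited intensity values of each spot were made with Agilent Feature Extraction 10.5.1.1, per the file headers, with background subtraction and spatial detrending on, and they were not normalized between arrays. The deposited value table holds intensity on a linear scale: it was equal to the software's total gene signal, within a relative difference of 1e-06, for all 208 features at or above 1 on the array labelled tumour and all 201 on the array labelled normal, and the 187 and 194 features below 1 were set to 1. Its column medians were 1.70 and 1.32, and it is neither centred nor a ratio.

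Spots of 1 probe that the software did not mark as outliers were averaged on the linear scale, leaving 4 to 20 spots per probe; 248 spots on the array labelled tumour and 336 on the array labelled normal were left out. No spot was saturated. A probe was detected where more than 50% of its spots were well above background, which held for 175 and 149 probes. Since this is under 50% of the 938 probes, each array was divided by its 75th percentile over the 140 probes detected on both arrays, 525.6 and 277.5 intensity units, then floored at its lowest signal of a detected probe and put on the log2 scale. The 75th percentiles differed 1.89-fold, a log2 ratio of 0.92 that any value without scaling includes. A miRNA's log2 ratio is the mean over its probes detected on both arrays, 1 probe for 30 miRNAs and more than 1 for 55. The calls are a rule of size, 2-fold or more, and not a test.

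The number of arrays limits the precision. The median spot CV of detected probes was 5.20% on the array labelled tumour and 6.33% on the array labelled normal, and the median spot SE of a log2 ratio was 0.04. Probes of 1 miRNA differed by a median of 0.05 and by at most 0.33. Negative control spots, 672 per array, had a mean of 1.21 and 2.64 intensity units, against 18.3 and 18.2 for the dimmest detected probe.

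The lists of miRNAs, 18 in all, the rule for naming miRNAs and 14 alternatives were fixed before the data were examined. Named miRNAs are the 10 highest and 10 lowest ratios at least 2-fold apart whose probes go the same way, up to 5 miRNAs per array detected there alone with the largest bound, the 5 brightest per array, and up to 4 measured members per list with the largest absolute ratio. The lists cover skeletal muscle, epithelium, leukocytes, red blood cells, stroma, endothelium, nerve, other organs, miRNAs often raised or often lowered in oral or head and neck squamous cell carcinoma, the clusters of miR-17 and miR-92a, the let-7, miR-15 and miR-16, miR-29 and miR-30 families, the Dlk1-Dio3 cluster, p53-linked miRNAs and hypoxia. They rest on general knowledge of the field. For lists with 3 or more measured members, 11 of the 18, the median was placed among 10000 random lists of the same size, each member replaced by a draw from the 21 measured miRNAs nearest in mean level. These percentiles describe the 2 arrays and are not p-values. The draws are independent, while list members from neighbouring genes or with similar probes can move together. The percentiles can therefore overstate how unusual a list is. The alternatives were other scalings, normexp with an offset of 50 on the mean and local background signals, the total gene signal, the deposited value table, other filters on dim probes, marked spots kept, other summaries over probes, and odd or even spots. Alternatives drew 2000 random lists each. A further 3 were chosen after seeing the data: scaling on positive control features, scaling without muscle miRNAs, and 1 detection limit for both arrays.

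miRNA names are those of the array design. For neighbouring genes, 346 of the 350 names matched a RefSeq gene table of the rat assembly GRCr8, while the array's grid names build rn4, so no coordinates are given. The steps were tested on simulated data made for the comparison of the 2 arrays: of 350 miRNAs 200 were given a change, and 48 of them were measured on both simulated arrays. All 18 with a log2 change of 1.5, all 14 with 2 and all 16 with 3 were recovered at 2-fold or more, and 0 of 36 miRNAs without a change were called, after removing a shift of 0.14 that the scaling left. Both simulated arrays were made from the array labelled normal with spot noise only, so they check the steps and not differences between samples. No planted log2 change was smaller than 1.5, and the shift was taken from miRNAs known to be unchanged, which real arrays do not give. Of 200 random lists of 5 miRNAs, drawn from the 36 without a change, 9 lay outside the central 95%. The simulated ratios of these 36 were independent, so this does not check lists whose members move together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.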

Results

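The study compared microRNA (miRNA) levels in squamous cell carcinoma of the rat tongue with those in normal rat tongue. Per the labels, male Sprague-Dawley rats aged 6 to 7 weeks drank the carcinogen 4NQO at 0.02 g/l, or distilled water, with 20 rats in each arm. Tissue was collected at the end of week 36, and RNA was extracted from 7 tumours and 7 normal tongue samples. The data analysed here are 2 arrays, 1 labelled tumour and 1 labelled normal, and the labels do not say whether either array held RNA of 1 animal or of several. Each array carried 938 probes for 350 rat miRNAs on 7000 spots. With 1 array per group there was no replicate check, so no test between groups was made, and every error given is the spread of spots within an array.

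On the array labelled tumour 104 of the 350 miRNAs were detected, and on the array labelled normal 88 were. Both arrays detected 85 miRNAs, and 243 were detected on neither. The 5 brightest miRNAs of the array labelled tumour were miR-1, miR-133b, miR-23a, let-7c and let-7a. Those of the array labelled normal were miR-21, miR-205, miR-23a, let-7c and miR-27a. Brightness depends on the probe as well as on the RNA, so these names rank signals and not abundances. Summed over all miRNAs, miR-1 and miR-133b gave 24.6% of the signal on the array labelled tumour and 2.67% on the array labelled normal. For miR-21 the shares were 2.61% and 23.6%.

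The design asks which miRNAs differ between the carcinoma and the normal tongue. Of the 85 miRNAs measured on both arrays, 11 were at least 2-fold higher on the array labelled tumour and 19 at least 2-fold lower, with 55 between. The highest ratio was that of miR-1, a miRNA of cardiac and skeletal muscle, at 13.2-fold higher (log2 ratio 3.72, spot SE 0.03). The lowest was that of miR-31, often raised in human oral carcinoma, at 15.2-fold lower (log2 ratio -3.93, spot SE 0.03). These directions go against what is commonly reported for oral carcinoma, so the arrays are called by their labels throughout, and each direction holds only as far as the labels do. The split of higher and lower calls depended on the scaling: it was 23 and 7 with the 75th percentile over all probes, 28 and 5 without scaling, and 18 and 8 with the muscle miRNAs left out of the percentile. Scaling on the array's positive control features gave 27 and 5.

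**Figure D1:**
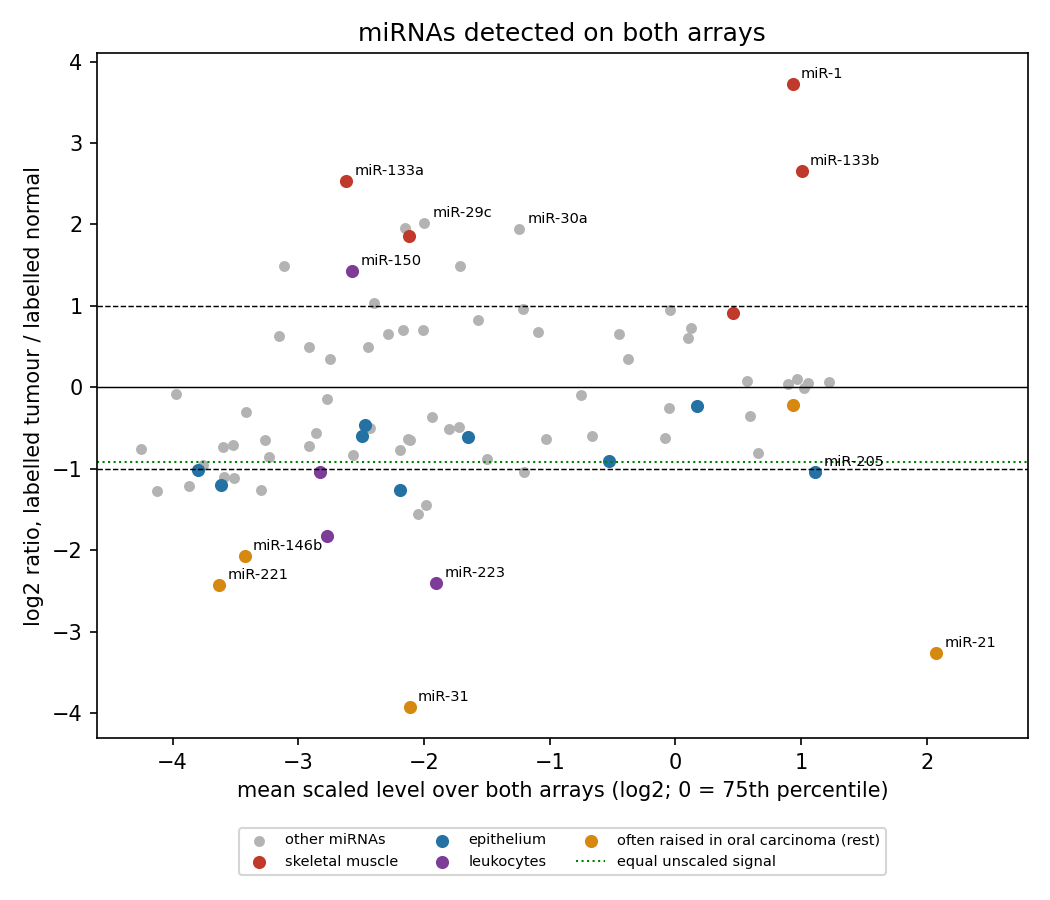
Each point is 1 of the 85 miRNAs detected on both arrays, with its mean scaled level on the x axis (log2, 0 is the 75th percentile) and its log2 ratio of the array labelled tumour over the array labelled normal on the y axis. Dashed lines mark 2-fold, the dotted line marks equal signal before scaling, and miR-1 at 3.72 and miR-31 at -3.93 are the extremes.

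Muscle miRNAs were higher on the array labelled tumour. All 5 measured members of the skeletal muscle list had ratios above 0, and 4 of them were at least 2-fold higher. Besides miR-1, these were miR-133b at 6.31-fold (log2 ratio 2.66), miR-133a at 5.78-fold (2.53) and miR-378 at 3.61-fold (1.85). The fifth, miR-206, named after its values were seen, was 1.88-fold higher (0.91). Another 2 members were detected on neither array. The list's median of 2.53 lay at the 99.98th percentile of 10000 random lists matched on mean level. The probes of miR-133a and miR-133b differ at 1 of 16 aligned bases, so signal of either miRNA can reach the probes of the other. Normexp background correction with its offset of 50 took miR-133a to 0.94 and miR-378 to 0.82, both under 2-fold.

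Several miRNAs found in many tissues were also higher on the array labelled tumour. In the miR-30 family all 5 measured members were above 0 and 3 were at least 2-fold higher: miR-30e (log2 ratio 1.96), miR-30a (1.94) and miR-30c (1.49). The family's median of 1.49 lay at the 98.1th percentile of matched random lists. Members of the miR-29 family, whose targets include collagen mRNAs, differed in size: miR-29c was 4.05-fold higher, against 0.73 for miR-29a and 0.66 for miR-29b on the log2 scale. The median of the miR-29 family, 0.73, lay at the 85.8th percentile. Probes of miR-29a and miR-29c differ at 1 of 20 aligned bases, and those of miR-30a and miR-30e at 1 of 16. The other miRNAs at least 2-fold higher were miR-10b (1.49), the lymphocyte miRNA miR-150 (1.43) and the erythroid miRNA miR-451 (1.04), the only measured member of the red blood cell list. Normexp brought miR-30e, miR-30c, miR-29c, miR-10b, miR-150 and miR-451 under 2-fold, with values of 0.87, 0.75, 0.97, 0.23, 0.38 and 0.27.

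Of the 18 miRNAs on the array from the list often raised in oral or head and neck squamous cell carcinoma, 7 were measured on both arrays and 6 of these were at least 2-fold lower on the array labelled tumour. miR-31 had a scaled level of 0.0592 on the array labelled tumour and 0.901 on the array labelled normal, where 1 is each array's 75th percentile. miR-21, raised in many carcinomas, was 9.60-fold lower (log2 ratio -3.26), miR-221 was 5.39-fold lower (-2.43) and the myeloid miRNA miR-223 was 5.31-fold lower (-2.41). The list's median of -2.41 lay at the 0.005th percentile of matched random lists. miR-221 rests on 1 probe, the dimmest detected on the array labelled tumour. Both without scaling and with normexp, 5 of the 7 were at least 2-fold lower. Without scaling the list's median was -1.49 and with normexp -1.34, and with no filter on dim probes it was -0.92 and lay inside the central 95% of random lists.

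The list often lowered in oral or head and neck squamous cell carcinoma went the other way. Of its 16 measured members, 14 had ratios above 0, 5 were at least 2-fold higher and 0 at least 2-fold lower, and its median of 0.78 lay at the 99.9th percentile. Its highest members were miR-1, miR-133b, miR-133a and miR-29c, of which the first 3 also belong to the muscle list. Without those 3, 11 of 13 members were above 0, 2 were at least 2-fold higher, and the median was 0.71. Without scaling, 11 of these 13 were at least 2-fold higher and their median was 1.63. With normexp 1 of them was, and their median was 0.35. Detection on the array labelled tumour alone added 4 members, and detection on the array labelled normal alone added 1, against 19 and 3 over all miRNAs.

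**Figure D2:**
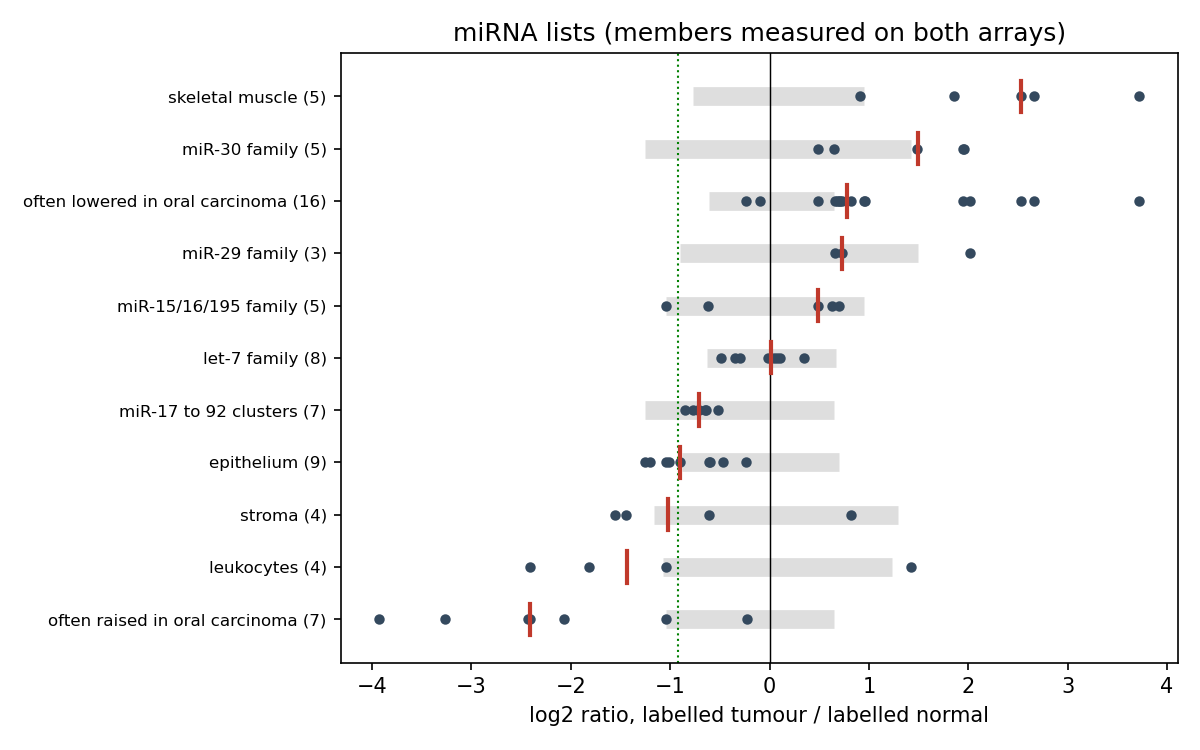
Each row is a list fixed before the data were examined, with the number of members measured on both arrays in brackets; points are members, red bars are list medians and grey bands are the central 95% of medians of random lists matched on level, on a log2 ratio axis. The dotted line marks equal signal before scaling, which lies close to the epithelium median of -0.90, while the skeletal muscle median is 2.53 and the median of miRNAs often raised in oral carcinoma is -2.41.

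Epithelial miRNAs were modestly lower on the array labelled tumour after scaling. All 9 measured members of the list were below 0 and 4 were at least 2-fold lower, among them miR-141 (log2 ratio -1.26) of the miR-200 family, which represses ZEB factors, miR-96 (-1.20), miR-205 (-1.04) and miR-183 (-1.01). The median of -0.90 lay at the 1.51th percentile of matched random lists, but it was 0.02 without scaling, so whether epithelial miRNAs were lower or level depended on the scaling. In the spots of odd number alone, the list no longer lay outside the central 95%.

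Leukocyte miRNAs went in both directions. Of 4 measured members, 3 were at least 2-fold lower on the array labelled tumour: miR-223, the blood cell miRNA miR-142-3p (log2 ratio -1.82) and miR-146a (-1.04), which is induced by NF-kB. The fourth was miR-150, which was 2.69-fold higher. Without scaling miR-142-3p was at -0.90 and miR-146a at -0.12 on the log2 scale, both under 2-fold. The median of -1.43 lay at the 0.245th percentile, and it lay inside the central 95% with the total gene signal, the deposited value table and no filter. miR-146b, which shares its seed with miR-146a, was 4.21-fold lower (-2.07).

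Stromal miRNAs also split. miR-199a-5p (log2 ratio -1.56, -0.63 without scaling) and miR-214 (-1.44, -0.52 without scaling) were at least 2-fold lower on the array labelled tumour after scaling. These 2 share a transcript in mesenchymal cells. miR-199a-3p was at -0.60 and the smooth muscle miRNA miR-143 at 0.82. The median of -1.02 lay at the 5.24th percentile, inside the central 95% of random lists. miR-126, the measured miRNA of the endothelium list, was at 0.68.

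The 7 measured members of the clusters of miR-17 and miR-92a lay between -0.85 and -0.52, with miR-106b lowest and with miR-92a at -0.77, miR-93 at -0.72 and miR-17 at -0.71. Their median of -0.71 lay at percentile 27.3 and turned to 0.21 without scaling and to 0.14 on the control features. The 8 let-7 family members lay between -0.49 and 0.35, with a median of 0.02 at the 59.7th percentile that was 0.94 without scaling; let-7e had the lowest ratio and let-7d the highest, and let-7i and miR-98 were at -0.35 and -0.30. let-7b was the 1 miRNA whose probes went different ways, and it is named after its values were seen. In the family of miR-15 and miR-16, miR-15b was 2.06-fold lower, but at -0.12 on the log2 scale without scaling. After scaling miR-16 was at -0.62, while miR-195 was at 0.70 and miR-322 at 0.63. That family's median of 0.49 lay at the 82.6th percentile and was -0.14 with normexp.

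Single miRNAs of the remaining lists were measured. The hypoxia miRNA miR-210 was 2.16-fold lower on the array labelled tumour (log2 ratio -1.11), miR-494 of the Dlk1-Dio3 imprinted cluster was 2.40-fold lower (-1.27), and miR-34a, a p53 target, was at -0.64. Without scaling miR-210 was at -0.19 and miR-494 at -0.34, both under 2-fold. Of the imprinted cluster, 5 other members were detected on the array labelled tumour alone and 0 on the array labelled normal alone. After scaling their bounds were at most 1.07-fold higher or no fold. Ratios between -0.92 and 0 turn positive without scaling, where miR-34a was at 0.28, miR-16 at 0.30 and miR-199a-3p at 0.32. No member of the nerve list or of the liver and pancreas list was measured on both arrays. Among the other lower miRNAs, miR-7a was 2.41-fold lower (-1.27, but -0.35 without scaling). miR-99b (-1.21) and miR-140* (-1.11) were chosen after their values were seen. Across the 16 alternatives, each of the 30 called miRNAs kept its sign wherever it had a value. Scaling by a common factor shifted ratios by at most 0.92, so it could not change the sign of a call. In all 16, 7 stayed at least 2-fold: miR-1, miR-133b and miR-30a higher, and miR-31, miR-21, miR-223 and miR-146b lower. miR-221 did so in the 14 that gave it a value, and was not measured on both arrays with all spots well above background or with even spots. Calls resting on 1 probe numbered 6 of the 11 higher and 10 of the 19 lower, among them miR-30a and miR-146b. The scaled level of miR-146b on the array labelled tumour, 0.0453, was near the lowest detected there, 0.0347.

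**Figure D3:**
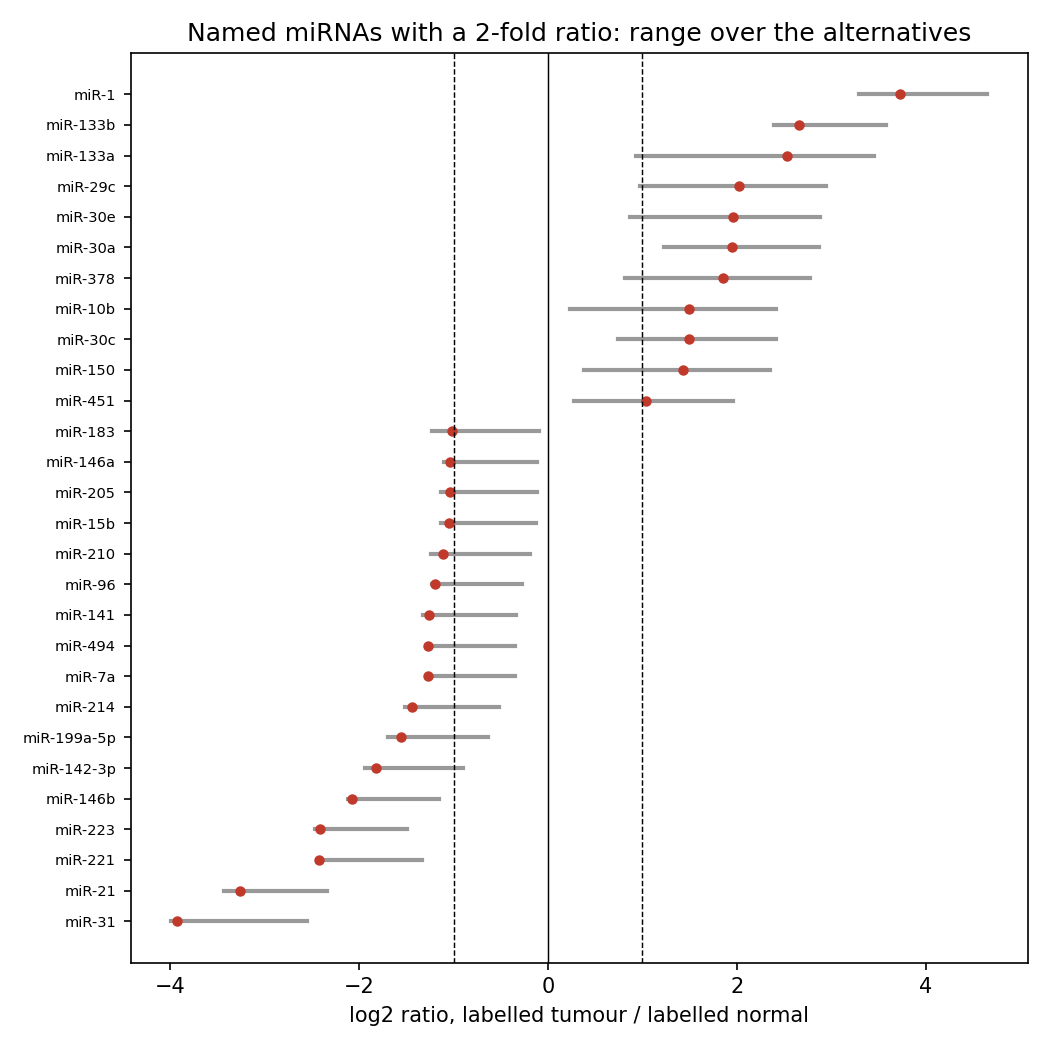
Red points are the log2 ratios of named miRNAs at least 2-fold apart on the 2 arrays, and grey bars run from the lowest to the highest value over the alternatives, for example from -3.99 to -2.55 for miR-31 and from 3.29 to 4.64 for miR-1. Dashed lines mark 2-fold, and no bar crosses 0. Scaling by a common factor shifts a value by at most 0.92, too little to bring a called one across 0.

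On 1 array only, 19 miRNAs were detected on the array labelled tumour and 3 on the array labelled normal. Fold values for these are lower bounds, computed against the higher of the miRNA's own signal and the lowest signal of a detected probe on the other array. On the array labelled tumour, miR-378* was at least 2.21-fold higher, miR-204 at least 2.16-fold, miR-128 at least 1.59-fold, miR-30a* at least 1.56-fold and miR-100 at least 1.32-fold. For 9 of the 19 the bound was under 1 and no fold is given. On the array labelled normal, miR-193 was at least 2.37-fold higher, miR-188 at least 2.20-fold and the epithelial miRNA miR-182 at least 1.97-fold. All these bounds hold only after scaling. Without it, each bound on the array labelled tumour would be 1.89-fold larger and each on the array labelled normal 1.89-fold smaller. With 1 scaled detection limit for both arrays the counts became 10 and 15. That limit is common only after scaling, since the dimmest detected probes were at 18.3 and 18.2 intensity units before it. The excess on the array labelled tumour thus depended on the scale of the limit.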

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

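The tests in this part were all chosen after the results they concern had been seen; the lists of miRNAs were fixed before.

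A signal appeared in features that no comparison used. Of the array's positive control features, 23 were examined and 19 were well above background on both arrays. These 19 had a median signal of 2526 intensity units on the array labelled tumour and 2158 on the array labelled normal, while no kind of negative control exceeded a mean of 3.72. By name they are of only 5 kinds, whose median unscaled log2 ratios, labelled tumour over labelled normal, ran from -0.25 to 0.25. What RNA the 19 features measure is not given in the sources used here. Their unscaled log2 ratios, labelled tumour over labelled normal, had a median of 0.072 and ran from -0.29 to 0.34, while the miRNA probes differed by 0.92 at the 75th percentile of those detected on both arrays, by 0.44 at that of all probes, and by 0.46 in the median miRNA.

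The first pattern is that miRNAs often raised in oral carcinoma were lower on the array labelled tumour, and miRNAs often lowered were higher; scaling as the cause is argued against by the raised list's median, which was at most -1.49 under the 6 other scalings. A larger share of muscle as the whole cause would lower all non-muscle miRNAs alike, but over the 7 and 9 members measured on both arrays the raised list's median lay -1.51 from the epithelium list's, or 4.28 SDs of that list, and with normexp, the narrowest gap for these members, -0.55 or 2.27 SDs. With no filter and every member on the array counted, both medians were -0.92, the raised list's being the ratio of the arrays' floors since 11 of its 18 members were detected on neither array. Several members of the epithelium list come from neighbouring genes with similar ratios, so an SD over that list can be too narrow a measure. Measured leukocyte miRNAs ran more widely, from -2.41 to 1.43, and stromal ones from -1.56 to 0.82. An exchange of the 2 labels stays open and cannot be told apart from a real difference: the 18 of 20 non-muscle members that went against their list's name are the pattern itself, and the miR-17 and miR-92a clusters, which share no measured member with those lists, had a median of -0.71 after scaling but 0.214 without it. The muscle list was also higher on the array labelled tumour, with a median of 2.53 and of 0.94 to 3.45 over the alternatives. How much muscle each sample held is not given in the sources used here, so these values do not decide it. Several often-lowered miRNAs are also expressed in muscle, the lists rest mainly on human tumours, and neither a mixed difference in cell types nor a real difference in these tumours was tested.

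The second pattern is that miRNA probes were brighter on the array labelled tumour, by 0.44 to 0.92 depending on the measure. A brighter array as a whole and a brighter miRNA fraction cannot be told apart: the median of the positive control features, 0.072, lay below all of these values, but the highest control reached 0.34 and the bright corner spots differed by 0.66. A few abundant muscle miRNAs could account for part of it, since the log2 ratio of the 75th percentiles was 0.61 without the muscle list against 0.92 with it. The content of miRNA in the RNA of each tissue was not tested.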

How the results depend on the processing

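The counts of calls moved with the scaling and with normexp. The median log2 ratio of the 85 miRNAs moved by 0.92 without scaling, by 0.48 with the 75th percentile over all probes, by 0.10 with quantile normalization and, chosen after seeing the data, by 0.85 on the positive control features and 0.31 without the muscle list. The number of miRNAs at least 2-fold higher on the array labelled tumour, 11, became 23 with the 75th percentile over all probes, 28 without scaling, 27 on the control features and 18 without the muscle list, 3 with normexp, 18 with the total gene signal and 18 with the deposited value table. The number at least 2-fold lower, 19, became 7, 5, 5 and 8 under the same scalings in that order, and 8 with normexp. The moves under these scalings follow from the common shift. Detection on the array labelled normal alone, 3 miRNAs, became 6 with the total gene signal. With that signal and with the deposited value table, the median log2 ratio of the 85 miRNAs moved by 0.23. Both also used the software's own detection, 126 and 110 miRNAs against 104 and 88, so their counts cover a different set of miRNAs. How much of the moves came from each was not tested. The normexp offset of 50 is added on both arrays, so it pulls the unscaled ratios of dim miRNAs towards equal signal. On the array labelled normal, unscaled signals summed over the 2 probes of each miRNA were 20.7 for miR-10b, 21.8 for miR-133a and 69.7 for miR-378. The offset is added to each spot, so these sums overstate the signal of a single probe beside it. How much of the normexp moves came from the offset was not tested. Normexp took the skeletal muscle median from 2.53 to 0.94 and miR-31 from -3.93 to -2.55. With 1 scaled detection limit for both arrays, chosen after seeing the data, the counts of miRNAs on 1 array alone, 19 and 3, became 10 and 15; the array labelled normal has the higher scaled limit, 0.0657 against 0.0347. Lists outside the central 95% numbered 6, and 4 to 6 under the alternatives. Skeletal muscle, the miR-30 family and the often-lowered list lay outside it under all 16, the often-raised and epithelium lists under 15 and the leukocyte list under 13. A scaling by a common factor shifts all ratios alike, so it could not change a percentile beyond the random draws. The median over probes repeated the main ratios, and the deposited value table repeated the results of the total gene signal. Without a filter, miRNAs dim on both arrays compare only the arrays' floors, at -0.92. Of the values of single miRNAs and lists under the alternatives, 431 stayed within the 95% range of their spot error and 538 moved beyond it, and 0 called values changed sign. Scaling by a common factor, a shift of at most 0.92, could not change the sign of a call. Signal over background limits the 30 miRNAs measured by 1 probe and the 22 detected on 1 array. No paired analysis was possible because each group has 1 array.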

Other observations

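The test in this part was chosen after the ratios had been seen.

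miRNAs whose genes neighbour each other had similar ratios on the 2 arrays. Within 10 kb, 39 pairs of measured miRNAs were neighbours, and 34 of them had probes differing at more than 2 bases. In the miR-200b, miR-200a and miR-429 group, chosen after its values were seen, the log2 ratios of the array labelled tumour over the array labelled normal were -0.61, -0.46 and -0.60. In the miR-17, miR-19b and miR-92a group, chosen likewise, they were -0.71, -0.65 and -0.77. These groups lay above 0 without scaling and when scaled on the positive control features. Pairs that stood apart were miR-133b and miR-206, at 2.66 and 0.91, miR-29b and miR-29c, at 0.66 and 2.02, and miR-1 and miR-133a, at 3.72 and 2.53.

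A hypothesis is that neighbouring miRNA genes may change together, as parts of shared transcripts. Over the 34 pairs with dissimilar probes the median absolute difference of log2 ratios was 0.28, and 0 of 10000 shuffles of the ratios over the measured miRNAs gave one as small; their central 95% ran from 0.65 to 1.57. The difference between neighbours does not depend on the scaling by a common factor. Pairs of 1 group share members, and the test describes these 2 arrays only. Shared sources in the same cell types, which would give the same pattern, were not tested apart from shared transcripts.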
